A study of Mus musculus with 15 samples.

How the data were processed

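RNA from sorted mouse liver endothelial cells was measured on 15 one-colour Agilent arrays, 3 for each of 5 sorted populations. According to the labels, total RNA was extracted with RNeasy columns, amplified with the Ovation Pico WTA System V2, and its cDNA was labelled with Cy3. The labels name Agilent Feature Extraction as the image software; the file headers give its version as 10.10.1.1 for the 6 EC-SP and EC-MP arrays and as 11.5.1.1 for the 9 arrays of the CD157 and CD200 subsets, which were also read on another scanner. The scanner files hold background-subtracted, spatially corrected spot values of Cy3 intensity on a linear scale, per the file headers. The deposited series table holds the same intensity multiplied by 1 constant per array, between 5.46 and 10.1, on a linear scale and without centring. What the authors based that constant on is not given in the sources used here. Its column medians were 256.5, 299.6 and 286.1 for EC-SP replicates 1 to 3, 299.5, 331.2 and 335.4 for EC-MP, 255.8, 278.4 and 252.3 for CD157+CD200+, 265.0, 293.0 and 262.8 for CD157-CD200+, and 218.3, 296.6 and 238.5 for CD157-CD200-.

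Values were read from the scanner files. Control spots were left out, spots the image software marked as non-uniform or as deviating from their replicates were set to missing (110 to 213 of 59305 spots per array), and no spot was saturated. Each value was the log2 of the processed signal minus the log2 of that array's 75th percentile, and spots of 1 probe were averaged. Of 55681 probes, 28059 carried the symbol of 21173 genes, assigned through RefSeq accessions and the 4 annotation revisions in the files, the newest first. The other 27622 probes, 16194 of them for genomic regions, kept their own names and were tested as features of their own. A probe was tested if the image software called it well above background on all 3 arrays of at least 1 group in the fit. This kept 34280 probes for EC-SP and EC-MP and 33835 for the subsets. The probe with the highest mean signal over the 15 arrays stood for each gene, which left 23971 and 23701 features, of which 14220 and 14364 had a gene symbol. Symbols were the identifiers used, and no coordinates were used.

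The fits were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), and Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the files. EC-SP and EC-MP were fitted on their 6 arrays and the subsets on their 9 arrays, since different scanners and software versions keep the 2 sets of arrays apart. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 over all features of a comparison. The tests are two-sided and moderated by limma. Standard errors are those of the fitted difference, with n = 3 arrays per group. Where a gene was not well above background on any array of 1 group, its fold is given as a lower bound, computed against the larger of its own signal and the lowest signal called well above background on each array. The adjusted p beside such a bound is that of the fitted difference, which used the signals at background, and not of the bound. In the subset fit, limma's moderated F test asked for any difference among the 3 subsets. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 40 lists with at least 5 tested members in each comparison. The tests were repeated with the correlation estimated from the data. In that setting camera also takes its p from the residual degrees of freedom of the fit, which are few with 3 arrays per group. A call lost there can therefore not be put down to correlation between genes alone. The numbers of called members are given over all features and adjusted over the list alone.

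The comparisons, tests, gene lists, alternatives and the rule for which genes are named were written down before the data were examined. For each comparison the rule takes the sort markers Bst1 and Cd200, the genes Pecam1, Cdh5 and Ptprc, and the dye efflux transporters. It then takes the 8 called genes with the largest log2 difference in each direction that moved the same way in all 3 same-numbered pairs, leaving out unnamed and predicted transcripts. It adds up to 3 called members of each list with the lowest adjusted p, or the member with the lowest p where none was called. Where this came to over 30 genes, some list members were left out. The EC-SP signature was the 200 features with the most positive and the 200 with the most negative moderated statistic for EC-SP minus EC-MP, among 22610 features tested in both fits.

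The labels number the replicates from 1 to 3 without saying what the numbers stand for. After the group means were removed, arrays with the same number correlated across features at r between 0.27 and 0.33 for EC-SP and EC-MP (3 pairs) and between 0.27 and 0.63 for the subsets (9 pairs). Arrays with different numbers gave r between -0.20 and -0.08 (6 pairs) and between -0.49 and 0.03 (18 pairs). Removing the means of 3 arrays pushes the latter below 0 where the former are above it, so they are not separate support. Arrays with the same number thus shared variation. The numbers coincide with the slide and the scan session, so pairing of the samples cannot be told apart from the slide, and a block for the number is also a block for the slide. The comparisons were fitted without this block as the main analysis and with it as an alternative.

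Alternatives were quantile normalization, normexp background correction (offset 50), no filter on dim probes, a filter asking for signal well above background on every array, the mean of a gene's probes, the replicate block, all 15 arrays in 1 fit, array weights, the authors' series table, leaving out each array in turn, a call that also asked for at least a doubling or halving, and other sizes of the EC-SP signature. The normexp alternative used the median spot and background signals, because the scanner files used here give medians in place of the mean spot signal planned for it. List tests under the series table, under normexp, with 1 array left out and with the replicate block and an estimated correlation together were added after seeing the data, and so was the test of whether the EC-SP minus EC-MP difference differs from the CD157+CD200+ minus CD157-CD200- difference. The fits were tested on simulated data, drawn with each feature's own mean and residual spread and no group difference, in which 100 features each were shifted by a log2 difference of 1 or 2. In the EC-SP and EC-MP fit 5% and 65% of these were called; in the subset comparisons 15% to 26% and 70% to 79% were. Of 74 to 110 calls 2 to 9 were false. A list of 20 shifted genes was found in each comparison, with camera p between 6.9e-34 and 4.1e-24, and of 50 lists of unshifted genes at most 1 passed. The simulated features were drawn independently, without correlation between genes or between same-numbered arrays. These rates therefore do not tell how the tests behave on real arrays, where such correlation was present. Figures were drawn with matplotlib 3.10.9.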

Results

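Gene expression was measured in 15 samples of endothelial cells sorted from mouse liver. Each of 5 populations had 3 samples: EC-SP and EC-MP, both from animals 8 weeks old, and 3 subsets defined by the surface proteins CD157 and CD200, namely CD157+CD200+, CD157-CD200+ and CD157-CD200-. The labels give EC-SP and EC-MP only as SP and MP. These are read here as the side and the main population, which the labels do not spell out. A side population is the fraction of cells that exports a DNA-binding dye through ABC transporters and so stains weakly. Between 57.3% and 69.4% of the spots on an array were well above background, and the 75th percentile of the signal lay between 157 and 297 intensity units. Within a group, arrays correlated across probes at r between 0.967 and 0.983, and the median absolute log2 difference between replicates was 0.25 to 0.44. The number of arrays, 3 per group, limits the precision of every value. The labels do not say whether the replicates come from separate animals, so the p-values measure only the spread between these samples, which may be technical.

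The comparison of EC-SP with EC-MP asked which genes mark the population from which endothelial stem cells were sought. Bst1, which encodes CD157, was higher in EC-SP by a log2 difference of 4.34 ± 0.24 (SE, n = 3 per group, adjusted p = 2.7e-05), with group means of 2.79 and -1.55 relative to the array's 75th percentile. Cd200, which encodes CD200, was higher by 3.39 ± 0.26 (adjusted p = 9.0e-05). The efflux transporters Abcb1a (4.48 ± 0.33, adjusted p = 8.1e-05) and Abcg2 (3.62 ± 0.21, adjusted p = 2.8e-05) rose with them. Of 20 sinusoidal marker genes 19 were called lower in EC-SP, and of 19 arterial marker genes 17 were called higher. Lyve1, a hyaluronan receptor of sinusoids and lymphatics, differed by -5.28 ± 0.26 (adjusted p = 1.9e-05) and the arterial semaphorin Sema3g by 3.15 ± 0.23 (adjusted p = 8.2e-05). In all, 3968 of 23971 features were called, 2184 higher and 1784 lower in EC-SP, and 3964 of them moved the same way in all 3 same-numbered pairs. Here and in the other comparisons, a call with 3 arrays per group nearly ensures such agreement, so it is not separate support. Of the 3968 called features, 2769 had a gene symbol, 1585 higher and 1184 lower.

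The general endothelial genes Pecam1 (0.80 ± 0.27, adjusted p = 0.077) and Cdh5 (0.10 ± 0.24, adjusted p = 0.84) and the leukocyte gene Ptprc (0.25 ± 0.24, adjusted p = 0.55) did not pass the test. Pecam1 did pass with the replicate block (adjusted p = 0.025), under normexp (adjusted p = 0.032) and without EC-MP replicate 3 (adjusted p = 0.049). Among 8 dye efflux transporters 5 rose and 1 fell (6 and 1 adjusted over the list alone), with a median log2 difference of 1.95 (adjusted p = 9.1e-05, adjusted p = 0.19 with an estimated correlation). Abcb1b, the second gene for P-glycoprotein, was at least 10.3-fold higher in EC-SP (adjusted p = 3.6e-05), and Abcb4 differed by 2.65 ± 0.24 (adjusted p = 0.00020). Abcc1 differed by 1.24 ± 0.25 (adjusted p = 0.010), whereas Abcc5 differed by -1.17 ± 0.22 (adjusted p = 0.0072). Abcc3 (0.72, adjusted p = 0.076) and Abcc4 (0.15, adjusted p = 0.78) were not called, and Abcc3 was called under normexp (adjusted p = 0.031).

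Among the genes with the largest differences in favour of EC-SP, Glycam1, a mucin-like ligand of L-selectin, differed by 8.56 ± 0.93 (adjusted p = 0.00051) and Igfbp3, a binding protein of insulin-like growth factors, by 7.09 ± 0.47 (adjusted p = 5.2e-05). The cytokine Il6 differed by 6.57 ± 0.42 (adjusted p = 4.2e-05) and the matrix protein gene Sparcl1 by 6.54 ± 0.37 (adjusted p = 2.7e-05). In EC-MP, Glycam1 and Il6 were well above background on 2 of 3 arrays and Igfbp3 on 1 of 3, as were Efhd1 (6.52 ± 0.57, adjusted p = 0.00017) and the semaphorin Sema7a (6.13 ± 0.49, adjusted p = 0.00011). Itih5, of the hyaluronan-binding inter-alpha-trypsin inhibitor family, was at least 32.8-fold higher (adjusted p = 1.7e-05), and the enkephalin precursor Penk at least 30.1-fold higher (adjusted p = 0.00018). In favour of EC-MP, the disintegrin-domain gene Adam23 was at least 100-fold lower in EC-SP (adjusted p = 2.9e-05) and the pentraxin Ptx3 at least 31.2-fold lower (adjusted p = 0.00011). Oit3 (-6.34 ± 0.32), the deoxyribonuclease gene Dnase1l3 (-5.70 ± 0.29), the lectin gene Clec4g (-5.70 ± 0.32), the integrin gene Itga8 (-5.64 ± 0.51), the scavenger receptor Stab2 (-5.38 ± 0.35) and the peptidase Dpp4 (-5.35 ± 0.31) had adjusted p between 1.9e-05 and 0.00021. In EC-SP, Dnase1l3 was well above background on 2 of 3 arrays and Itga8 on 1.

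By vessel type, 19 of 20 sinusoidal genes fell in EC-SP (19 adjusted over the list alone), with a median log2 difference of -3.64 (adjusted p = 8.9e-23, adjusted p = 0.19 with an estimated correlation). Arterial genes moved the other way: 17 of 19 rose and 1 fell, the same numbers adjusted over the list alone, and the median was 1.80 (adjusted p = 8.0e-12, adjusted p = 0.19 with an estimated correlation). The chemokine Cxcl12 was higher by 4.22 ± 0.32 (adjusted p = 9.1e-05) and the Notch ligand Jag2 at least 23.0-fold higher (adjusted p = 0.00015). Of 20 genes of large-vessel, continuous endothelium 10 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.95 (adjusted p = 6.9e-05, adjusted p = 0.25 with an estimated correlation). The matrix Gla protein Mgp differed by 4.35 ± 0.30 (adjusted p = 5.4e-05). Among 20 venous and central vein genes 4 rose and 10 fell (6 and 11 adjusted over the list alone), with a median of -0.98 (adjusted p = 0.020, adjusted p = 0.25 with an estimated correlation, adjusted p = 0.105 with the replicate block and 0.0505 under the authors' series table). Of its members, Wnt2 was at least 8.57-fold lower (adjusted p = 9.5e-05) and the R-spondin Rspo3 differed by -3.25 ± 0.28 (adjusted p = 0.00016). The endothelial selectin Sele differed by 3.41 ± 0.25 (adjusted p = 7.9e-05). In the lymphatic list, which shares Lyve1 and Flt4 with the sinusoids, 6 of 9 genes fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -2.44, or -2.00 with undetected genes at their bounds (adjusted p = 6.3e-05, adjusted p = 0.19 with an estimated correlation).

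Other functional groups also differed, but some of their lists share genes with the vessel lists. Notch1, Notch4, Dll4, Jag1, Jag2, Hey1 and Hey2 are in both the Notch and the arterial list. Stab1, Stab2, Mrc1, Fcgr2b, Ctsl and Ehd3 are in both the scavenging and the sinusoidal list. Sele, Selp and Ackr1 are in both the leukocyte adhesion and the venous list. In the Notch list 9 of 16 genes rose and none fell (10 adjusted over the list alone), with a median of 0.89 (adjusted p = 2.0e-05, adjusted p = 0.25 with an estimated correlation). The Notch target Hey1 differed by 2.88 ± 0.25 (adjusted p = 0.00017) and the ligand Dll4 by 1.90 ± 0.27 (adjusted p = 0.0018). Leukocyte adhesion and inflammation genes rose in 13 of 22 cases and fell in 2 (15 and 2 adjusted over the list alone, median 1.08, adjusted p = 1.0e-05, adjusted p = 0.25 with an estimated correlation). The chemokine Cxcl2 differed by 2.42 ± 0.23 (adjusted p = 0.00027). Immediate-early genes, which also respond to tissue dissociation, rose in 8 of 24 cases (11 adjusted over the list alone, median 0.67, adjusted p = 0.00022, adjusted p = 0.29 with an estimated correlation). Nr4a2 differed by 2.99 ± 0.26 (adjusted p = 0.00018), Myc by 2.97 ± 0.28 (adjusted p = 0.00025) and Fosl2 by 2.60 ± 0.24 (adjusted p = 0.00022). Interferon-stimulated genes rose in 11 of 20 cases (13 adjusted over the list alone, median 0.80, adjusted p = 4.9e-05, adjusted p = 0.25 with an estimated correlation). The antiviral Rsad2 differed by 2.00 ± 0.27 (adjusted p = 0.0015). Of 11 genes of antigen presentation on MHC class II 6 rose and none fell (7 and 1 adjusted over the list alone, median 1.47, adjusted p = 0.0066, adjusted p = 0.19 with an estimated correlation). The invariant chain Cd74 differed by 2.91 ± 0.43 (adjusted p = 0.0022). Of 25 genes of endocytosis and scavenging 11 fell and 2 rose (11 and 2 adjusted over the list alone, median -0.78, adjusted p = 2.0e-06, adjusted p = 0.25 with an estimated correlation). The zonation factors Gata4 (-2.51 ± 0.21, adjusted p = 0.00013) and Maf (-3.37 ± 0.28, adjusted p = 0.00014), both regulators of sinusoidal identity, were lower in EC-SP, and the arterial factor Sox17 was higher (2.19 ± 0.22, adjusted p = 0.00030).

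Markers of other cell types moved with these groups. Of 13 cholangiocyte markers 11 rose in EC-SP (11 adjusted over the list alone), with a median of 1.84 (adjusted p = 6.2e-09, adjusted p = 0.19 with an estimated correlation). The bile duct keratin Krt19 differed by 2.62 ± 0.29 (adjusted p = 0.00052) and the osteopontin gene Spp1 by 2.65 ± 0.31 (adjusted p = 0.00072). Of 11 Kupffer cell markers 4 fell (7 adjusted over the list alone), with a median of -1.14 (adjusted p = 0.00022, adjusted p = 0.19 with an estimated correlation). Of 16 hepatocyte markers 3 rose and 3 fell (3 and 4 adjusted over the list alone, median -0.38, adjusted p = 0.31). Albumin, Alb, differed by 1.23 ± 0.22 (adjusted p = 0.0056) and the fibrinogen chain Fgb by -1.91 ± 0.34 (adjusted p = 0.0059, adjusted p = 0.058 under normexp). Without a filter on dim probes 2279 features were called. With the authors' series table the median of all features moved from -0.01 to -0.17, and the calls split into 1649 higher and 2495 lower, so that the share higher was 39.8% in place of 55.0%. The sinusoidal, arterial, Notch and cholangiocyte lists were called in the same direction there.

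The comparison of CD157+CD200+ with CD157-CD200- set the extremes of the antibody sort against each other. The sort was visible in the RNA: Cd200 was at least 320-fold higher in CD157+CD200+ (adjusted p = 7.8e-09), and Bst1 was higher by a log2 difference of 5.73 ± 0.25 (SE, n = 3 per group, adjusted p = 5.5e-07), with 2 of the 3 CD157-CD200- arrays well above background for it. The von Willebrand factor gene Vwf, a product of large-vessel endothelium, was higher by 7.86 ± 0.27 (adjusted p = 1.9e-07), and the scavenger receptor Stab2 of sinusoids differed by -7.07 ± 0.19 (adjusted p = 5.5e-08). All 21 sinusoidal genes tested were lower. A total of 3601 of 23701 features were called, 1917 higher and 1684 lower in CD157+CD200+, and 3598 of them moved the same way in all 3 same-numbered pairs. With the replicate block 6938 were called. The majority lay on the lower side with only probes well above background on every array (1373 higher, 1468 lower).

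**Figure D1:**
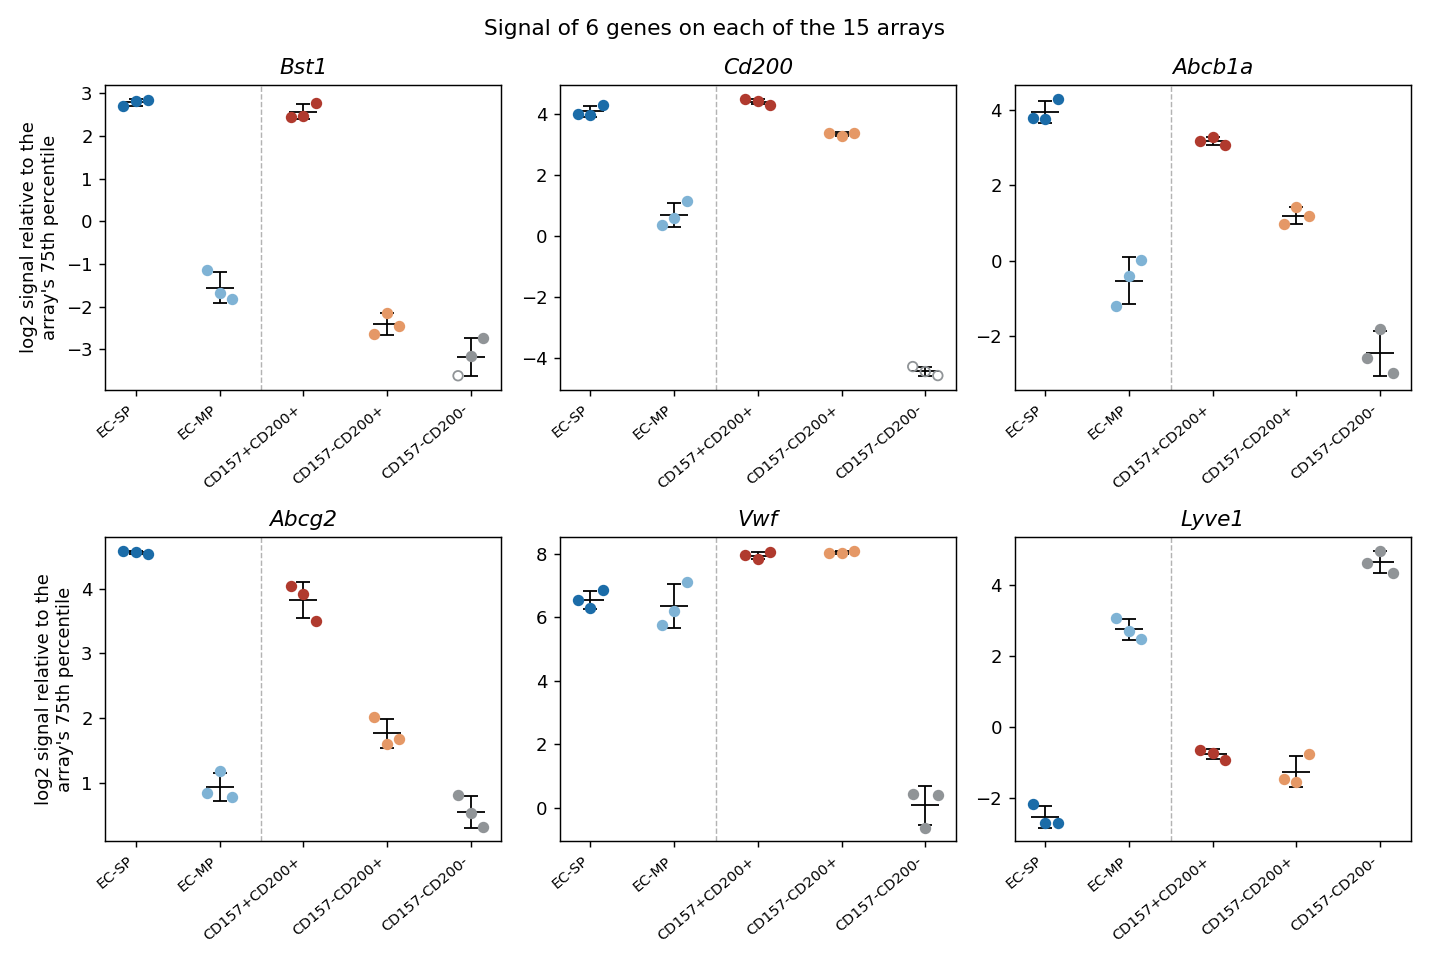
Signal of Bst1, Cd200, Abcb1a, Abcg2, Vwf and Lyve1 on each of the 15 arrays, as log2 relative to the array's 75th percentile (points, open where the spot was not well above background, bars, mean and SD of 3 arrays). Abcg2 was higher in EC-SP (mean 4.56) than in EC-MP (0.94) and higher in CD157+CD200+ (3.82) than in CD157-CD200+ (1.77) and CD157-CD200- (0.56).

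Pecam1 was higher in CD157+CD200+ by 1.09 ± 0.17 (adjusted p = 0.0015), while Cdh5 (-0.16 ± 0.22, adjusted p = 0.75) and Ptprc (-0.20 ± 0.42, adjusted p = 0.86) did not pass the test. Among the 8 efflux transporters 4 rose and 2 fell (5 and 2 adjusted over the list alone), with a median of 1.54, or 1.40 with undetected genes at their bounds (adjusted p = 0.0092, adjusted p = 0.093 with an estimated correlation). Abcb1a differed by 5.64 ± 0.28 (adjusted p = 1.2e-06), Abcg2 by 3.26 ± 0.22 (adjusted p = 7.1e-06) and Abcb4 by 2.58 ± 0.20 (adjusted p = 2.1e-05), and Abcb1b was at least 4.93-fold higher (adjusted p = 9.0e-06). The members that fell were Abcc3 (-1.47 ± 0.17, adjusted p = 0.00023) and Abcc4 (-0.89 ± 0.18, adjusted p = 0.0077). Abcc1 (0.51, adjusted p = 0.072, or 0.012 with the replicate block) and Abcc5 (0.07, adjusted p = 0.89) were not called.

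Among the genes with the largest differences in favour of CD157+CD200+, the fibronectin-domain gene Fndc1 was at least 120-fold higher (adjusted p = 4.1e-07), the myosin-linker gene Myrip at least 72.1-fold (adjusted p = 8.3e-09), Igfbp3 at least 67.5-fold (adjusted p = 3.9e-07) and Lysmd2 at least 57.0-fold (adjusted p = 1.5e-07). The epithelial membrane protein gene Emp1 differed by 8.32 ± 0.37 (adjusted p = 6.0e-07), and the collagen gene Col8a1, measured on 1 of 3 CD157-CD200- arrays, by 7.67 ± 0.60 (adjusted p = 2.0e-05). In the other direction Adam23 was at least 277-fold lower in CD157+CD200+ (adjusted p = 1.3e-06), the orphan nuclear receptor Esrrb at least 45.9-fold lower (adjusted p = 3.7e-05) and the hepatocyte growth factor gene Hgf at least 28.6-fold lower (adjusted p = 2.0e-05). Dnase1l3 (-7.43 ± 0.22), Gatm, of creatine synthesis (-5.97 ± 0.27), the mannose receptor Mrc1 (-5.67 ± 0.25) and Oit3 (-5.62 ± 0.18) had adjusted p between 1.1e-07 and 6.7e-07.

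The sinusoidal list had a median of -3.83 with 21 of 21 members called lower, also adjusted over the list alone (adjusted p = 1.1e-30, adjusted p = 0.0069 with an estimated correlation). Large-vessel genes rose in 17 of 20 cases and fell in 2 (17 and 2 adjusted over the list alone, median 2.04, adjusted p = 9.6e-15, adjusted p = 0.0046 with an estimated correlation). Fbln2, a fibulin of vessel walls, was higher by 6.81 ± 0.20 (adjusted p = 1.1e-07) and Mgp by 6.61 ± 0.26 (adjusted p = 3.8e-07). Arterial genes rose in 12 of 19 cases and fell in 1 (14 and 2 adjusted over the list alone, median 2.19, adjusted p = 6.2e-10, adjusted p = 0.0069 with an estimated correlation). The gap junction gene Gja5, which encodes connexin 40, differed by 5.95 ± 0.18 (adjusted p = 1.3e-07). Of 20 venous and central vein genes 8 rose and 1 fell (8 and 2 adjusted over the list alone). Their median was 0.02 with a mean of 1.15 (adjusted p = 0.019, adjusted p = 0.31 with an estimated correlation, adjusted p = 0.126 with the replicate block). With the replicate block and an estimated correlation together no list was called in any of the 4 pairwise comparisons. In this one the sinusoidal, large-vessel and arterial lists then had adjusted p of 0.11, 0.075 and 0.081. That setting leaves the fewest residual degrees of freedom, which by itself raises p. The loss of every call there therefore does not show that correlation between genes accounts for the lists. The selectin Selp differed by 5.29 ± 0.26 (adjusted p = 1.0e-06) and the receptor Kit by -3.58 ± 0.20 (adjusted p = 2.2e-06).

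**Figure D2:**
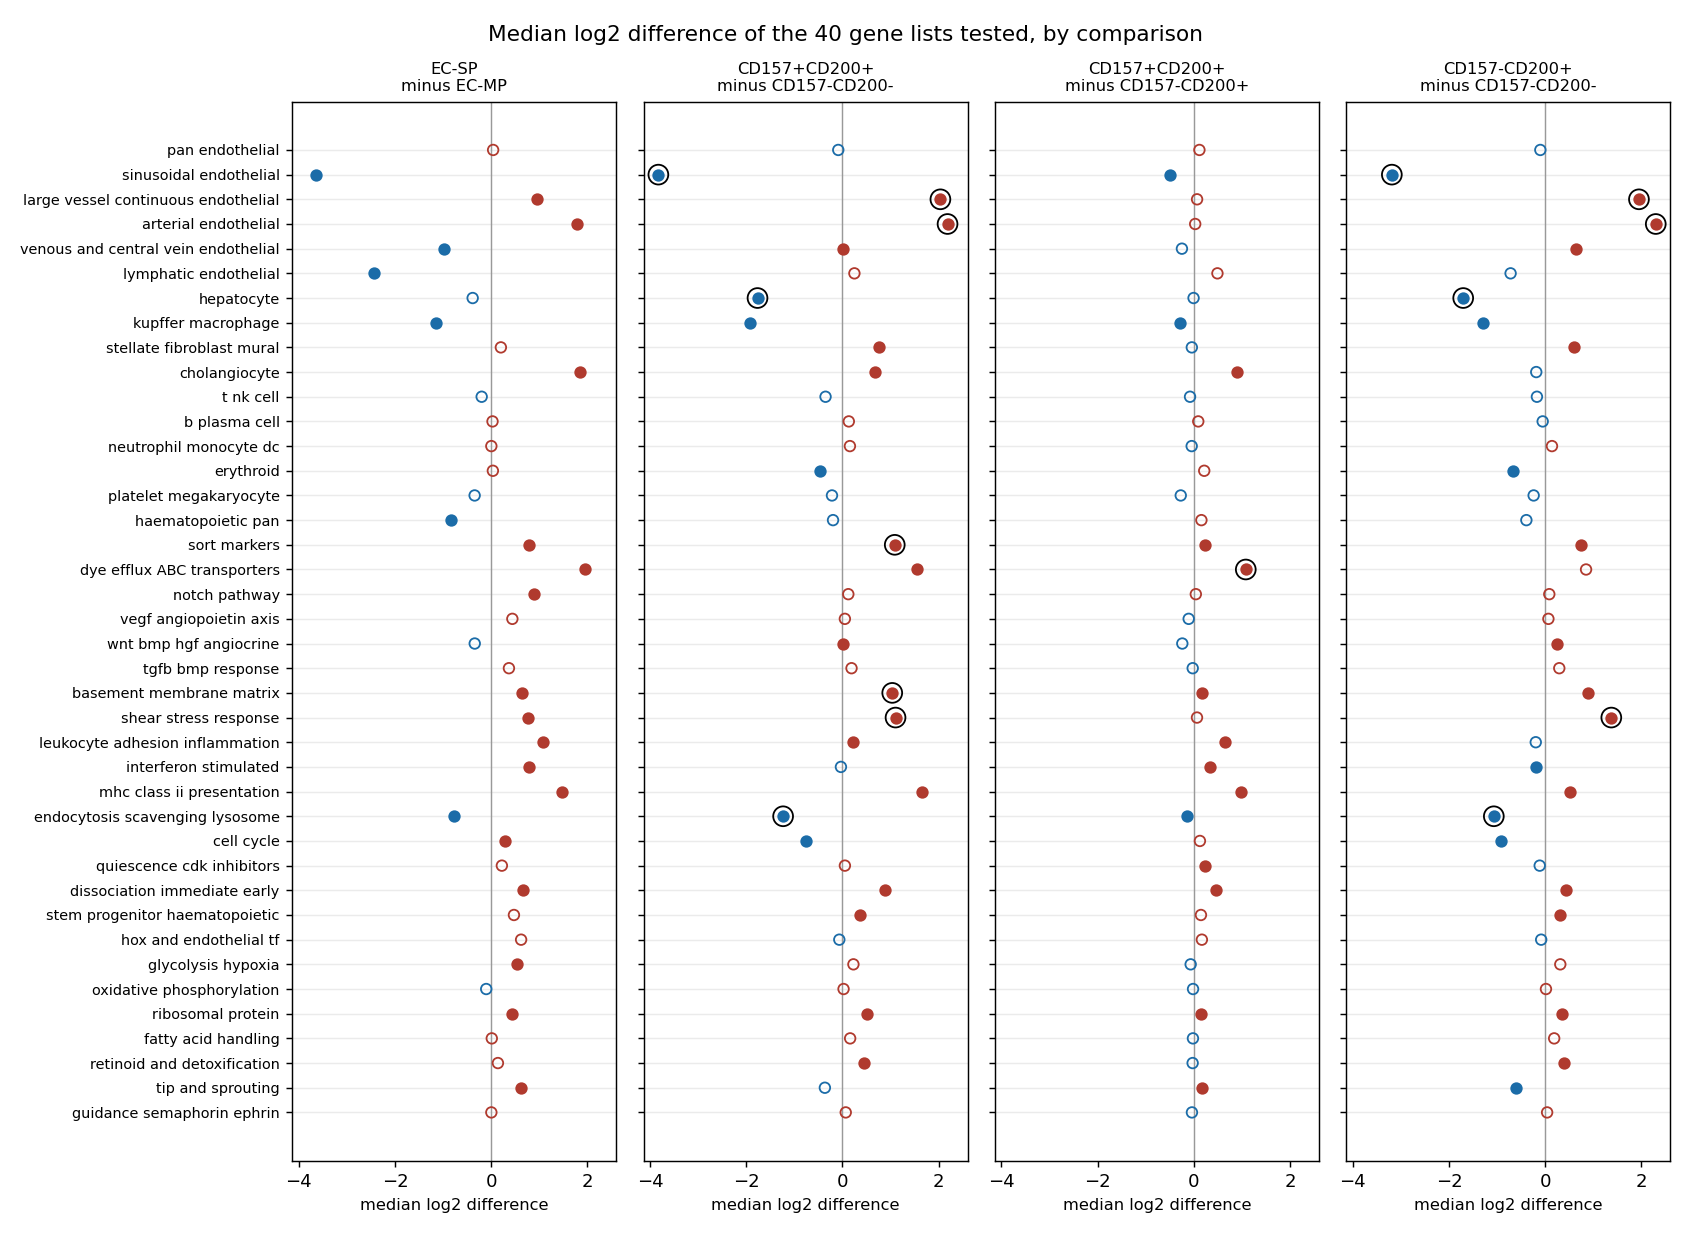
Median log2 difference of the members of each of the 40 gene lists tested, in the 4 pairwise comparisons (filled, camera adjusted p under 0.05, black ring, also with an estimated correlation, red, median above 0, blue, below 0). The sinusoidal list had the lowest median in every panel, from -3.83 in CD157+CD200+ minus CD157-CD200- to -0.50 in CD157+CD200+ minus CD157-CD200+.

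Genes of the basement membrane and matrix rose in 12 of 24 cases and fell in 5 (15 and 7 adjusted over the list alone, median 1.04, adjusted p = 1.9e-05, adjusted p = 0.022 with an estimated correlation). Vwf, Fbln2, Fbln5, Mgp and Eln of this list are also in the large-vessel list. Genes that respond to shear stress rose in 11 of 14 cases and fell in 1 (12 and 1 adjusted over the list alone, adjusted p = 5.4e-08, adjusted p = 0.031 with an estimated correlation). The endothelin gene Edn1, also in the large-vessel list, differed by 6.23 ± 0.31 (adjusted p = 1.2e-06) and the oxidoreductase Nqo1 by 3.02 ± 0.21 (adjusted p = 9.6e-06). The scavenging list fell in 17 of 25 cases and rose in 2, also adjusted over the list alone (median -1.23, adjusted p = 3.3e-11, adjusted p = 0.015 with an estimated correlation). MHC class II genes rose in 6 of 11 cases (7 with 1 lower adjusted over the list alone, median 1.65, adjusted p = 0.0035, adjusted p = 0.22 with an estimated correlation). The beta chain H2-Ab1 differed by 2.13 ± 0.27 (adjusted p = 0.00042). Immediate-early genes rose in 13 of 24 cases (16 with 1 lower adjusted over the list alone, median 0.89, adjusted p = 2.5e-07, adjusted p = 0.20 with an estimated correlation). Cell cycle genes fell in 6 of 22 cases (10 adjusted over the list alone, median -0.75, adjusted p = 0.00014, adjusted p = 0.20 with an estimated correlation), among them the nucleotide reductase subunit Rrm2 (-1.48 ± 0.27, adjusted p = 0.0042). The bone morphogenetic protein gene Bmp4 was higher by 6.97 ± 0.25 (adjusted p = 2.0e-07), and Maf was lower (-3.70 ± 0.25, adjusted p = 7.0e-06).

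Hepatocyte and Kupffer cell markers were higher in CD157-CD200-. This did not hold for all other liver cells: the stellate and mural list had a median of 0.77 and the mesothelial list, too small for the list test, one of 0.56. Medians of the blood cell lists lay on both sides of 0. They were -0.46 for erythroid, -0.35 for T and NK cell, -0.22 for platelet and -0.20 for pan-haematopoietic markers. For B and plasma cells the median was 0.13, and for neutrophils, monocytes and dendritic cells 0.16. Of 17 hepatocyte markers 13 were lower in CD157+CD200+ (14 adjusted over the list alone, median -1.77, adjusted p = 2.8e-08, adjusted p = 0.049 with an estimated correlation). Fgb differed by -2.78 ± 0.26 (adjusted p = 5.9e-05). Of 15 Kupffer cell markers 9 were lower (10 adjusted over the list alone, median -1.91, adjusted p = 1.8e-07, adjusted p = 0.077 with an estimated correlation). The Kupffer lectin Clec4f differed by -2.04 ± 0.27 (adjusted p = 0.00060). The alpha globin gene Hba-a1, which has a near-identical copy, differed by -3.69 ± 0.33 (adjusted p = 4.3e-05). Cholangiocyte markers had a median of 0.69 with 1 of 13 called higher, also adjusted over the list alone (adjusted p = 0.010, adjusted p = 0.29 with an estimated correlation).

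The comparison of CD157+CD200+ with CD157-CD200+ asked what CD157 marks among CD200-positive cells. Of 23701 features 248 were called, of which 190 were higher and 58 lower in CD157+CD200+, all in the same direction in the 3 same-numbered pairs. Bst1 differed by 4.98 ± 0.25 (SE, n = 3 per group, adjusted p = 0.00011). The efflux transporter Abcg2 was higher by 2.05 ± 0.22 (adjusted p = 0.0026), and the cytokine Il6 by 3.86 ± 0.25 (adjusted p = 0.00049). The sinusoidal gene Oit3 differed by -2.10 ± 0.18 (adjusted p = 0.0010).

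Cd200 itself was higher by 1.06 ± 0.16 (adjusted p = 0.013), a call that ended under quantile normalization (adjusted p = 0.082) and without replicate 1 or 2 of CD157+CD200+ (adjusted p = 0.077 and 0.068) or of CD157-CD200+ (adjusted p = 0.068 and 0.077). Pecam1 (0.24, adjusted p = 0.87), Cdh5 (-0.01) and Ptprc (0.00) did not pass the test. Of the 8 efflux transporters 4 rose and none fell (6 adjusted over the list alone, median 1.08, adjusted p = 1.6e-09, adjusted p = 0.022 with an estimated correlation and 0.23 with the replicate block as well). Abcb1a differed by 1.98 ± 0.28 (adjusted p = 0.011) and Abcb4 by 1.40 ± 0.20 (adjusted p = 0.012). Without CD157+CD200+ replicate 1, CD157-CD200+ replicate 1 or CD157+CD200+ replicate 2 the adjusted p rose to 0.057, 0.057 and 0.060 for Abcb1a and to 0.057, 0.063 and 0.065 for Abcb4. Abcb1b differed by 1.59 ± 0.28 (adjusted p = 0.028). Without replicates 1, 2 and 3 of CD157+CD200+ its adjusted p was 0.080, 0.13 and 0.083, and without those of CD157-CD200+ it was 0.14, 0.083 and 0.085. Abcc3 (0.76, adjusted p = 0.081, or 0.034 with the replicate block) and Abcc4 (0.60, adjusted p = 0.25, or 0.031 with the replicate block) were not called, nor were Abcc1 (-0.01) and Abcc5 (-0.18).

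In the list of the largest differences in favour of CD157+CD200+, Penk was higher by 5.70 ± 0.67 (adjusted p = 0.0043) and Itih5 by 4.47 ± 0.33 (adjusted p = 0.00062), each measured on 2 of 3 CD157-CD200+ arrays. The activin subunit gene Inhba differed by 4.65 ± 0.53 (adjusted p = 0.0038) and the thrombospondin gene Thbs1 by 4.36 ± 0.38 (adjusted p = 0.0010). The substance P receptor gene Tacr1 was at least 9.07-fold higher (adjusted p = 0.00050) and the Ras regulator Rasal1 at least 3.34-fold (adjusted p = 0.00070). In the other direction, the alkaline phosphatase gene Alpl differed by -4.82 ± 0.44 (adjusted p = 0.0013, 2 of 3 CD157+CD200+ arrays well above background), the growth factor Igf2 by -3.20 ± 0.42 (adjusted p = 0.0080), Aif1l by -2.89 ± 0.37 (adjusted p = 0.0065) and Serpinf1, which encodes pigment epithelium-derived factor, by -2.87 ± 0.29 (adjusted p = 0.0022). Tmem178 was at least 15.8-fold lower (adjusted p = 0.0040), and Gap43 at least 3.08-fold lower (adjusted p = 0.0035, or 0.061 under normexp). Rbm24 was at least 3.24-fold lower (adjusted p = 0.014), with 0.26 under normexp, 0.052, 0.067 and 0.060 without replicates 1, 2 and 3 of CD157+CD200+ and 0.066 without CD157-CD200+ replicate 2. Ptchd1 was at least 2.51-fold lower (adjusted p = 0.011), with 0.47 under normexp, 0.057 and 0.053 without replicates 1 and 2 of CD157-CD200+ and 0.055 without CD157+CD200+ replicate 2.

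The leukocyte adhesion list rose in 6 of 22 cases (11 with 1 lower adjusted over the list alone, median 0.64, adjusted p = 8.8e-13, adjusted p = 0.10 with an estimated correlation). The chemokine receptor Ackr1 of venules differed by 2.37 ± 0.32 (adjusted p = 0.0086). Immediate-early genes rose in 2 of 24 cases (3 adjusted over the list alone, median 0.47, adjusted p = 2.5e-08, adjusted p = 0.22 with an estimated correlation). The growth regulator Myc differed by 2.10 ± 0.28 (adjusted p = 0.0083). Matrix genes rose in 2 of 24 cases (5 with 1 lower adjusted over the list alone, median 0.17, adjusted p = 0.0041, adjusted p = 0.10 with an estimated correlation). The laminin chain Lamb1 differed by 3.05 ± 0.31 (adjusted p = 0.0021). Of 11 MHC class II genes H2-DMb1 rose, by 2.37 ± 0.23 (adjusted p = 0.0017), and adjusted over the list alone 4 rose and 1 fell (median 0.98, adjusted p = 0.00071, adjusted p = 0.26 with an estimated correlation). The sinusoidal list fell in 3 of 21 cases (9 adjusted over the list alone, median -0.50, adjusted p = 4.4e-11, adjusted p = 0.095 with an estimated correlation). Large-vessel genes (median 0.07, adjusted p = 0.26) and arterial genes (median 0.03, adjusted p = 0.99) were not called as lists.

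Among markers of other cell types, none of 13 cholangiocyte genes was called over all features and 9 rose adjusted over the list alone (median 0.89, adjusted p = 1.8e-08, adjusted p = 0.12 with an estimated correlation). The hepatocyte list had a median of -0.00 (adjusted p = 0.83), and the Kupffer list one of -0.28 (adjusted p = 0.0041, adjusted p = 0.29 with an estimated correlation, 0.067 without CD157-CD200+ replicate 1 and 0.18 without CD157+CD200+ replicate 3). The count of 248 was sensitive to single arrays: it was 104 and 111 without CD157+CD200+ replicates 1 and 2, and 124 and 132 without CD157-CD200+ replicates 1 and 2. It was 727 with the replicate block, 465 with array weights and 160 with only probes well above background on every array.

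The comparison of CD157-CD200+ with CD157-CD200- asked what CD200 marks among cells without CD157. Of 20 large-vessel genes 17 were called higher in the CD200-positive cells, and of 21 sinusoidal genes 20 were called lower. Vwf was higher by a log2 difference of 7.96 ± 0.27 (SE, n = 3 per group, adjusted p = 2.2e-07) and Stab2 differed by -6.84 ± 0.19 (adjusted p = 1.3e-07). Cd200 was at least 154-fold higher (adjusted p = 1.3e-08). Bst1 differed by 0.76 ± 0.25 (adjusted p = 0.092), with 2 of 3 CD157-CD200- arrays well above background, and was called with the replicate block (adjusted p = 0.028) and without CD157-CD200- replicate 3 (adjusted p = 0.034). In total 2807 of 23701 features were called, 1495 higher and 1312 lower in CD157-CD200+, all of them in the same direction in the 3 same-numbered pairs.

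Pecam1 was higher by 0.85 ± 0.17 (adjusted p = 0.0079), and Cdh5 (-0.15, adjusted p = 0.82) and Ptprc (-0.20, adjusted p = 0.90) were not called. The transporters Abcb1a (3.65 ± 0.28, adjusted p = 2.5e-05), Abcg2 (1.21 ± 0.22, adjusted p = 0.0049) and Abcb4 (1.18 ± 0.20, adjusted p = 0.0039) rose, and Abcc3 (-2.23 ± 0.17, adjusted p = 2.0e-05) and Abcc4 (-1.49 ± 0.18, adjusted p = 0.00041) fell. Abcb1b was at least 1.64-fold higher (adjusted p = 0.00032, or 0.15 under normexp). Abcc1 (0.52, adjusted p = 0.081, or 0.013 with the replicate block) and Abcc5 (0.26, adjusted p = 0.56) were not called. As a list the transporters did not pass (median 0.85, or 0.62 with undetected genes at their bounds, adjusted p = 0.068), except under quantile normalization (adjusted p = 0.043). Fndc1 was at least 134-fold higher (adjusted p = 5.0e-07), Samd5 at least 73.4-fold (adjusted p = 7.9e-07) and Myrip at least 59.5-fold (adjusted p = 1.3e-08). Col8a1 (8.23 ± 0.60) and the cytochrome gene Cyp1b1 (7.90 ± 0.88), each measured on 1 of 3 CD157-CD200- arrays, and Bmp4 (7.53 ± 0.25) had adjusted p of 1.7e-05, 0.00026 and 1.8e-07. Besides Stab2, the named genes with the strongest decreases, at adjusted p between 1.4e-07 and 0.00014, were Adam23 (-8.19 ± 0.47), Dnase1l3 (-7.14 ± 0.22), Gatm (-6.37 ± 0.27), Lyve1 (-5.90 ± 0.25), Slc9a9 (-5.63 ± 0.38), Esrrb (-5.61 ± 0.57) and the purine receptor P2ry1 (-5.20 ± 0.37). Of these, Adam23 and Esrrb were well above background on 1 of 3 CD157-CD200+ arrays and Slc9a9 on 2.

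The sinusoidal list fell in 20 of 21 cases, also adjusted over the list alone (median -3.19, adjusted p = 5.8e-31, adjusted p = 0.0070 with an estimated correlation). Large-vessel genes rose in 17 of 20 cases and fell in 1, also adjusted over the list alone (median 1.95, adjusted p = 5.5e-17, adjusted p = 0.0031 with an estimated correlation and 0.055 with the replicate block as well). Fbln2 differed by 6.97 ± 0.20 (adjusted p = 1.3e-07). Arterial genes rose in 11 of 19 cases and fell in 2 (12 and 2 adjusted over the list alone, median 2.30, adjusted p = 4.6e-09, adjusted p = 0.0070 with an estimated correlation). Gja5 differed by 6.10 ± 0.18 (adjusted p = 1.3e-07). Venous and central vein genes rose in 10 of 20 cases and fell in 4 (11 and 5 adjusted over the list alone, median 0.64, adjusted p = 0.0047, adjusted p = 0.22 with an estimated correlation), and here Rspo3 was higher, by 4.95 ± 0.28 (adjusted p = 3.6e-06). Shear stress genes rose in 9 of 14 cases and fell in 1, also adjusted over the list alone (median 1.38, adjusted p = 9.9e-08, adjusted p = 0.034 with an estimated correlation). Edn1 differed by 6.68 ± 0.31 (adjusted p = 1.0e-06). The scavenging list fell in 15 of 25 cases and rose in 1 (17 and 1 adjusted over the list alone, median -1.07, adjusted p = 1.7e-12, adjusted p = 0.011 with an estimated correlation). Cell cycle genes fell in 9 of 22 cases (12 with 1 higher adjusted over the list alone, median -0.91, adjusted p = 2.1e-06, adjusted p = 0.14 with an estimated correlation). Rrm2 differed by -1.90 ± 0.27 (adjusted p = 0.0011) and the cyclin Ccna2 was at least 6.17-fold lower (adjusted p = 0.00014). The leukocyte adhesion list was not called (median -0.19, mean 0.04, adjusted p = 0.47), and its member Ackr1 differed by -2.79 ± 0.32 (adjusted p = 0.00032).

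As in the other contrast with CD157-CD200-, hepatocyte and Kupffer cell markers were lower, whereas the stellate and mural list had a median of 0.60 and the mesothelial list, too small for the list test, one of 0.08. Medians were -0.39 for pan-haematopoietic, -0.24 for platelet, -0.17 for T and NK cell and -0.05 for B and plasma cell markers. Neutrophil, monocyte and dendritic cell markers had a median of 0.14. Of 17 hepatocyte genes 15 fell (15 with 1 higher adjusted over the list alone, median -1.70, adjusted p = 8.2e-11, adjusted p = 0.034 with an estimated correlation). Of 15 Kupffer genes 8 fell (9 adjusted over the list alone, median -1.29, adjusted p = 2.1e-06, adjusted p = 0.10 with an estimated correlation), and of 7 erythroid genes 3 fell (4 adjusted over the list alone, median -0.68, adjusted p = 0.00052, adjusted p = 0.074 with an estimated correlation). Cholangiocyte markers were not called (median -0.18, adjusted p = 0.31). With the replicate block 5282 features were called. The majority lay on the lower side under normexp (1334 higher, 1428 lower) and with only probes well above background on every array (1040 higher, 1157 lower).

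Any difference among the 3 subsets was called for 3305 of 23701 features, 2591 of them with a gene symbol, and for 6350 with the replicate block.

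The last comparison asked whether the genes that set EC-SP apart from EC-MP, in the 6 arrays of that sort, also set the subsets apart in the other 9 arrays. The 200 features highest in EC-SP had a median log2 difference of 2.97 between CD157+CD200+ and CD157-CD200-, and the 200 lowest in EC-SP one of -1.84, which gave a distance of 4.81 between the medians. Of the former 198 were higher in CD157+CD200+ and 176 were called higher, with 1 called lower. Of the latter 172 were lower and 137 were called lower, with 11 called higher. The camera p was 8.5e-83 for the high list and 5.7e-44 for the low list, and 2.7e-05 and 0.00021 with an estimated correlation. Between CD157+CD200+ and CD157-CD200+ the medians were 1.22 and -0.73 (camera p = 8.4e-83 and 2.8e-55, 2.7e-05 and 0.00011 with an estimated correlation). Between CD157-CD200+ and CD157-CD200- they were 1.64 and -1.24 (camera p = 2.2e-43 and 1.9e-23, 0.00018 and 0.0012 with an estimated correlation).

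**Figure D3:**
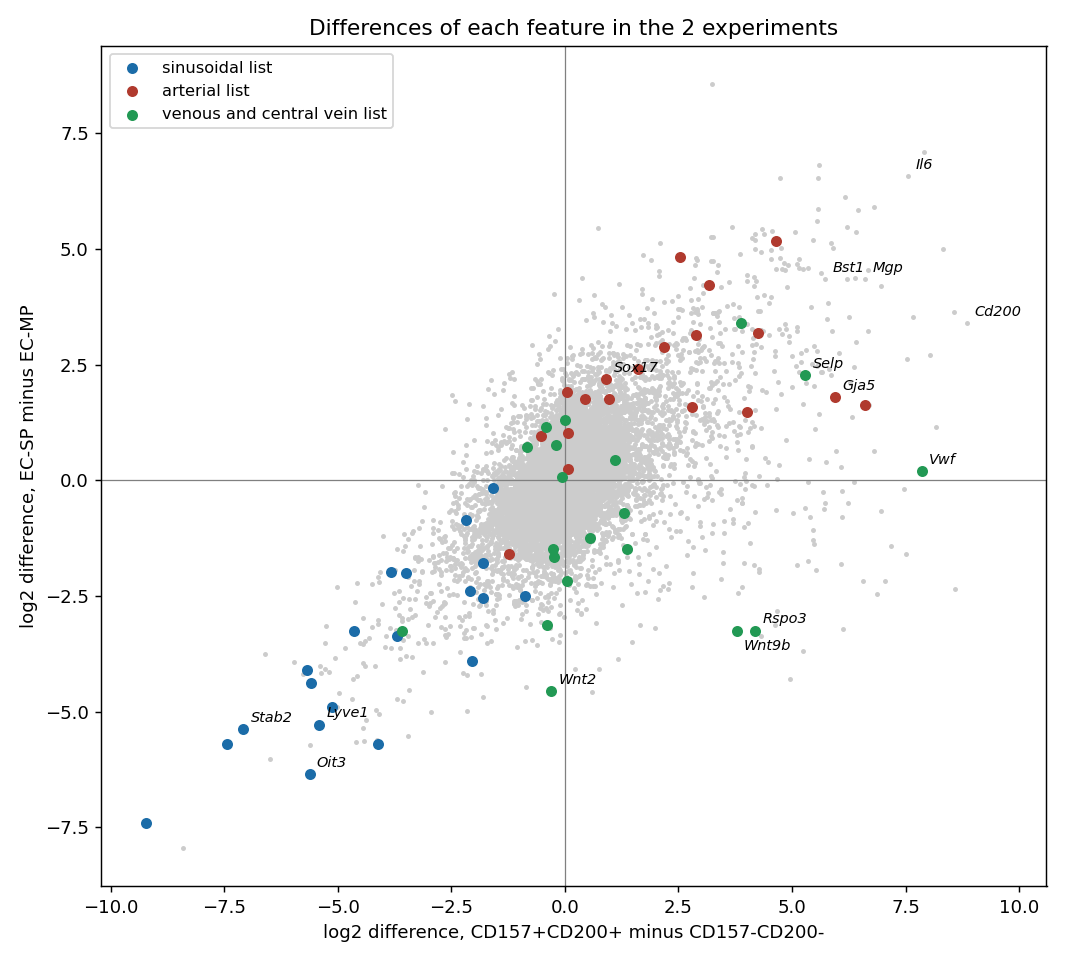
Log2 difference of each feature between EC-SP and EC-MP (y axis) against that between CD157+CD200+ and CD157-CD200- (x axis), both fitted also where a group was at background; grey, all features tested in both; coloured, members of 3 gene lists. Lyve1 lay low on both axes (-5.28 and -5.41), whereas Rspo3 lay at -3.25 and 4.18.

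Across 22610 features tested in both fits, the EC-SP minus EC-MP and the CD157+CD200+ minus CD157-CD200- differences correlated at Pearson's r = 0.58 and Spearman's rho = 0.50; features are not independent replicates. Called higher in both were 862 features, where 166.1 would overlap if the calls were independent, and called lower in both were 655, against 115.0. Another 110 were called in opposite directions, against 276.8. Abcb1a, Abcg2 and Il6 were higher in both, and Lyve1, Stab2, Oit3 and Dnase1l3 were lower in both. Bst1 and Cd200 were also higher in both, but the subsets were sorted on their proteins, so there they only check the sort. The distance of 4.81 was 3.17 under normexp and 1.29 when all called features made up the signature.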

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

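The list tests under normexp, under the authors' series table, with 1 array left out and with the block and an estimated correlation together were chosen only after the results were seen. The number of features called between EC-SP and EC-MP was 3968, fell to 2279 without a filter on dim probes, where more features were tested, and lay between 3167 and 5255 under the other alternatives that kept all arrays. The count of 3167 came from the stricter call that also asked for at least a doubling or halving. With the replicate block, which is at once the slide block, the counts went from 3601 to 6938 for CD157+CD200+ against CD157-CD200-, from 248 to 727 for CD157+CD200+ against CD157-CD200+, from 2807 to 5282 for CD157-CD200+ against CD157-CD200-, and from 3305 to 6350 for any difference among the subsets. Of the features called without the block, 3589, 245 and 2792 in the 3 pairwise subset comparisons were also called with it, as were 3837 for EC-SP against EC-MP. For CD157+CD200+ against CD157-CD200+ the count was also 160 with only probes well above background on every array and 465 with array weights. For the counts under the block, the array weights and both filters the cause was not tested. With 1 array left out, so that a group kept 2 arrays and limma pooled the spread, the counts were 2701 to 3330 for EC-SP against EC-MP. For the subset comparisons, in the order above, they were 2664 to 3312, 104 to 195, 2005 to 2647 and 2442 to 3040. The counts of 104, 111, 124 and 132, less than 248 by more than 1.5 times, came without replicates 1 and 2 of CD157+CD200+ and replicates 1 and 2 of CD157-CD200+. The signature distance of 4.81 kept its sign and its call, at 4.69 to 5.82 with 1 array left out and 1.29 to 6.37 under the other alternatives, the lowest with all called features as the signature and the highest with 100 features per direction. No named gene or list that was called changed to a call in the opposite direction. Of 160 list tests 79 were called. Of these 79, 64 lost their call with an estimated correlation, 10 with the replicate block and all 79 with both together, which left 0 called in each comparison. For EC-SP against EC-MP 0 kept it with an estimated correlation alone. The call was lost by 5 under quantile normalization (5 other lists gained one), by 2 under the series table (2 gained) and by 1 under normexp (8 gained). With 1 array left out, 33 of 960 tests, on called and uncalled lists alike, lost it and 16 gained one. Of 412 named-gene tests, on called and uncalled genes alike, 16 gained a call with the replicate block (1 lost it) and 9 under normexp (13 lost). Another call was gained by 1 under quantile normalization (5 lost), by 2 with the mean of a gene's probes (5 lost) and by 2 under the series table (5 lost). With 1 array left out 181 of 2472 lost it and 5 gained one. Signal over background set the other limit: with 57.3% to 69.4% of the spots well above background, a gene at background in 1 group has only a lower bound for its fold.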

Other observations

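Of the tests in this part, those of the effect difference between the 2 sets of arrays, of the Kupffer and cholangiocyte lists against a general loss of endothelial cells, and all of those of the large-vessel pattern were chosen only after the result was seen. Functions not described above also differed between EC-SP and EC-MP. Glycolysis and hypoxia genes rose in EC-SP in 6 of 22 cases (6 adjusted over the list alone, median 0.53, adjusted p = 0.00038, adjusted p = 0.25 with an estimated correlation), among them the glucose transporter Slc2a1 (3.71 ± 0.21, adjusted p = 2.7e-05) and the glycolytic regulator Pfkfb3 (1.86 ± 0.25, adjusted p = 0.0014). Genes of tip cells and sprouting rose in 7 of 18 cases and fell in 2 (8 and 2 adjusted over the list alone, median 0.62, adjusted p = 0.011, adjusted p = 0.25 with an estimated correlation). The cell cycle regulator Rgcc differed by 5.25 ± 0.28 (adjusted p = 2.4e-05), the chemokine receptor Cxcr4 by 4.82 ± 0.46 (adjusted p = 0.00025) and the urokinase receptor Plaur by 3.40 ± 0.22 (adjusted p = 4.8e-05). Cxcr4, Dll4 and Unc5b of the tip cell list are also in the arterial list. Cell cycle genes rose in 4 of 20 cases (4 adjusted over the list alone, median 0.29, adjusted p = 0.023, adjusted p = 0.25 with an estimated correlation), with the replication genes Mcm7 (1.67 ± 0.27, adjusted p = 0.0034) and Pcna (1.43 ± 0.25, adjusted p = 0.0052) among them. In CD157+CD200+ against CD157-CD200-, genes of stem and progenitor cells rose in 6 of 17 cases and fell in 2 (7 and 2 adjusted over the list alone, median 0.36, adjusted p = 0.020, adjusted p = 0.11 with an estimated correlation). Cd34, also in the large-vessel list, was higher by 3.82 ± 0.18 (adjusted p = 9.1e-07) and Procr, the protein C receptor, by 2.99 ± 0.36 (adjusted p = 0.00034).

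The EC-SP minus EC-MP difference was tested against the CD157+CD200+ minus CD157-CD200- difference in 1 fit of all 15 arrays. Of 22559 features 1314 differed, and 3477 differed with the replicate block. Of the 1314, the EC-SP minus EC-MP difference was the more positive for 564 and the more negative for 750. Among cell cycle genes the EC-SP minus EC-MP difference was the more positive in 7 of 20 cases and the more negative in none. The median gap between the 2 differences was 1.13 there. Rrm2 was higher in EC-SP by 1.41 and differed by -1.48 in the subsets (difference 2.89, adjusted p = 0.00032). For 12 of 20 venous and central vein genes the EC-SP minus EC-MP difference was the more negative and for 2 the more positive (median -1.62). Of 20 large-vessel genes this held for 9 and 0 (median -0.97). A more negative difference need not mean a lower level in EC-SP than in EC-MP. Among these genes Mgp had levels of 6.51 in EC-SP and 2.16 in EC-MP, and Rspo3 levels of 1.24 and 4.49. Among the features called in opposite directions, Rspo3 and Wnt9b, well above background on every array of the 4 groups, were picked after their values were seen: their differences between the 2 effects were -7.43 ± 0.41 (adjusted p = 6.8e-08) and -7.05 ± 0.43 (adjusted p = 1.0e-07).

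The 6 arrays of 2 groups of 3 make 10 splits, too few for a share under 0.05. Of these 10 splits 1, the real one, gave as many called features in each pairwise comparison: 3968 for EC-SP against EC-MP and 3601 for CD157+CD200+ against CD157-CD200-, with 0 in every other split of either. For CD157+CD200+ against CD157-CD200+ it was 248 against a highest other of 2, and for CD157-CD200+ against CD157-CD200- 2807 against 1. In both, the highest of the other splits that parted all 3 same-numbered pairs gave 0. Every other split of a pair of populations mixes both in each group, so their real differences enter the residual spread. Few calls there therefore do not tell how many calls noise alone would give. The signature distance of 4.81 was likewise reached by 1 of 10 splits, with 1.79 as the highest other and 1.78 among those that parted all pairs. For any difference among the subsets, 1 of 100 splits, the real one, reached 3305, and the highest other gave 3030, so that chance can be excluded only over splits that mostly ignore the pairing. The split with 3030 was 1 of 2 that kept the 3 CD157-CD200- arrays together, and no split that parted these arrays gave more than 497. Only 11 of the splits, the real one included, parted every triplet of same-numbered arrays, too few for a share under 0.05, and the highest other of these gave 2282.

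Cholangiocyte markers were higher in EC-SP than in EC-MP, with a median of 1.84 (SE of the median 0.28 over 13 genes), and Krt18 was among those with the highest signal (level 2.90 against 0.76, relative to the 75th percentile). A general loss of endothelial cells in EC-SP would raise markers of every other cell type, and the Kupffer median was -1.14 (SE of the median 0.45, 11 genes). That SE treats genes as independent, and the list was not called with an estimated correlation, so the test does not decide. The pan-endothelial median was 0.04. Other medians lay on both sides of 0: 0.20 for stellate and mural and 0.58 for mesothelial markers, -0.34 for platelet and -0.83 for pan-haematopoietic markers. Biliary cells sorted along with EC-SP stay open as a candidate source: a second biliary list, sharing 0 genes with the others, had a median of 1.90 with 8 of 13 tested genes called higher. Its members with the highest signal in EC-SP were Dmbt1 (level 3.65 against 0.97) and Itgb4 (1.86 against -1.51), though signals of different probes do not rank abundance. Of its 18 genes 6 were well above background on every array of both groups, and Sctr lay lowest, at -0.71 (adjusted p = 0.16). Expression of these genes by the EC-SP cells themselves was not tested and stays open, and the labels describe no gate that would remove biliary cells beyond calling the cells endothelial.

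Hepatocyte, Kupffer and haemoglobin transcripts were higher in CD157-CD200- than in CD157+CD200+. Fewer endothelial cells in CD157-CD200- as the whole cause would raise markers of every other cell type alike. The cholangiocyte median was 0.69 (SE of the median 0.09, 13 genes), against -1.77 (SE 0.30) for hepatocytes, and the pan-endothelial median was -0.09. The stellate and mural median (0.77) and the T and NK cell median (-0.35) lay on opposite sides of 0. The second biliary list had a median of 0.30, with 3 of 13 genes called higher and 1 lower. These SEs treat genes as independent, and biliary cells sorted with CD157+CD200+ could raise the cholangiocyte list by themselves, so the test does not decide. Cholangiocyte markers were also higher in CD157+CD200+ than in CD157-CD200+ (median 0.89), but in CD157-CD200+ against CD157-CD200- the cholangiocyte and hepatocyte lists still lay apart, at -0.18 (SE 0.13) and -1.70 (SE 0.26). RNA carried over from hepatocytes stays open as a candidate source: a second hepatocyte list, sharing 0 genes with the others, had a median of -1.30 with 12 of 23 tested genes called lower, and -1.62 with 12 of 23 in CD157-CD200+ against CD157-CD200-, whose arrays are the same in both contrasts. Of its 26 genes 17 were well above background on every array of both groups. Its members Apoc1 (level 2.32 against 3.32) and C3 (2.73 against 3.02), which had high signals, were not called in CD157+CD200+ against CD157-CD200-, while Apoc1 was called lower in CD157-CD200+ (-1.62, adjusted p = 0.0076). A difference between the endothelial cells themselves was not tested, and the labels describe no gate against hepatocytes or Kupffer cells beyond calling the cells endothelial.

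Large-vessel genes and some venous and central vein genes (8 of 20 called, list median 0.02) were higher in CD157+CD200+ than in CD157-CD200-, and for 20 members of these lists the EC-SP minus EC-MP difference was the more negative, though Wnt2, Nr2f2, Ephb4 and Car8 among them lay lower in CD157+CD200+ too. Compression of folds on the EC-SP and EC-MP arrays would shrink every list. The ratio of the median absolute log2 differences, EC-SP and EC-MP over the subsets, was 0.917 for the sinusoidal list and 0.511 for the large-vessel list. The lists were thus not smaller to a like degree. The ratio sets different populations against each other, whose true differences need not be equal, so it does not decide on compression. Large-vessel cells in both EC-SP and EC-MP stay open as a candidate explanation: genes at least 32-fold higher in CD157-CD200+ than in CD157-CD200-, chosen without 1 CD157-CD200- array, lay in EC-MP above their level on that array by medians of 4.35, 4.15 and 3.92 for replicates 1 to 3 (73 of 76, 72 of 76 and 76 of 80 genes). Signals at background on that array entered as measured, without a bound, so these medians are not exact folds. The central 95% of 10000 random lists matched on level in the other 2 arrays ended at 0.98, 0.59 and 0.71. Vwf, among the large-vessel genes with the highest signal, had levels of 6.55 in EC-SP, 6.35 in EC-MP and 0.08 in CD157-CD200-. For the 20 members that make up the pattern, chosen partly on the same CD157-CD200- arrays, the median in EC-MP was 1.78 (17 above CD157-CD200-), short of a verdict either way; how the cells of the 2 experiments were sorted, which cannot be told apart from the comparison across the 2 sets of arrays, stays open, as does a biological difference, neither of them tested.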
